A study of Saccharomyces cerevisiae with 20 samples.

How the data were processed

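The samples were 20 sequencing libraries from SK1 yeast, 10 of polyadenylated mRNA and 10 of ribosome footprints. Each mRNA library had a footprint library of the same strain, temperature and replicate number. Cells grew in YEPD with aeration at 30C or 37C and were harvested at an optical density of 0.6 after 1 min with 100 uM cycloheximide. Footprints were made from fragments of 28 to 31 nt and mRNA libraries from fragments of 50 nt. The groups were the helicase expressed, DED1 or DBP1, at each temperature, with replicates 1, 2 and 3 at 30C and 1 and 2 at 37C. Group and replicate were taken from the sample labels.

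The authors deposited a single table of RPKM values, mapped reads scaled by gene length and library depth, for 6679 genes in all 20 libraries. Per the submitters' processing notes, Bowtie2, CASAVA and bcl2fastq 2.17 were used. The genome build, the counting tool and the treatment of reads shared by paralogs are not given in the sources used here. The table has a second header line. In 2 column names it miswrites a digit of the number that all samples of a strain share. It also calls 1 mRNA column a footprint column. The sample labels were followed in each case.

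Depth was recovered from the steps between low RPKM values. With coding lengths shortened by 60 nt, the values were whole reads within a tolerance of 0.02 in all libraries for 5071 of the 6325 genes with any reads. With other lengths, chosen gene by gene to give whole reads, the number was 6141, or 97.1%. Depth came to 3.94 to 9.69 M reads per mRNA library and 4.82 to 9.39 M reads per footprint library. A single read in a gene of 1 kb therefore stands for 0.103 to 0.254 RPKM. Gene names came from the RefSeq annotation of strain S288C, release R64, which was used for names and coding lengths only, and is another strain than SK1. It matched 5994 of 6679 genes, or 89.7%, and the other 685 kept their systematic names. Of the 6679 genes, 354 had no reads in any library.

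Values were analysed as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, as linear models over all 10 libraries of an assay with 1 mean per group, followed by eBayes with an intensity trend. A gene was tested in an assay when its mean was at least 5 RPKM there, and for translation efficiency when it was so in both assays. Translation efficiency was tested in one model over all 20 libraries, as the footprint effect minus the mRNA effect. The comparisons were DBP1 with DED1 cells at each temperature, 37C with 30C in each strain, and the difference between the strains' temperature effects. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 counted as changed, with no limit on fold. Folds are those of RPKM + 1, so they understate the ratio of the mean RPKM where a group lies near 0. Efficiency of the expressed helicase was compared by an exact permutation test over cultures.

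The genes named in the text were picked by a rule. It took up to 6 genes per direction with the largest changes among called genes with a mean of at least 20 RPKM that changed the same way in each pair of cultures. It also took up to 4 members per gene list by smallest adjusted p, and the swapped genes. This choice after the tests leaves the printed folds of the largest changes somewhat too large.

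Gene lists for 33 processes, such as stress responses, respiration and protein synthesis, were fixed before the data were examined. A further 3 lists, used only in the closing section, were chosen after the values had been seen. Lists with at least 5 tested members were tested with camera in limma. The planned test had a preset correlation between genes of 0.01, and its alternative a correlation estimated from the residuals. With the preset, 154 of 380 list tests passed. List p-values in the text are those with the estimate unless stated otherwise. That estimate rests on few libraries per group, and none of the 380 tests passed with it. A list that did not pass is therefore not shown to be unchanged. Adjustment was also made over the members of a list alone.

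The procedure was tested on simulated data with known changes put into random genes with a mean of at least 20 RPKM. All genes of an assay were given the same spread between cultures, the median of the real genes. The mRNA and footprint values varied independently. Genes with a larger spread were not represented, so recovery for them was not measured. For mRNA between strains, 86.57% of 1.5-fold changes were recovered at 30C and 71.64% at 37C, and all 2-fold changes were. For translation efficiency between strains, 50.75% of 1.5-fold and 95.52% of 2-fold changes were recovered at 30C, against 25.37% and 91.04% at 37C. For translation efficiency between temperatures, 29.85% of 1.5-fold changes were recovered in DED1 cells and 40.30% in DBP1 cells.

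Alternatives were pseudocounts of 0.1 and 5, no filter beyond a mean above 0, a filter at a mean of 20 RPKM, and median-of-ratios scaling between libraries in place of the deposited scaling. Others were a block for the replicate number, a fit of only the groups compared, and the omission of each culture in turn. Precision weights on the recovered reads were added after the data had been seen. A count-based tool had been planned for a table of counts and was not run, because the table holds RPKM. For translation efficiency the block was the culture. The mRNA and footprint libraries of a culture deviated together from their group means, with r from 0.24 to 0.65 and a median of 0.51 over 10 pairs, and were therefore treated as pairs in that fit. Nothing in the table was left out of the tests apart from genes under the filter. The values of 1 gene picked by the naming rule are not reported here. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 did the remaining work.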

Results

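Ded1 and Dbp1 are related DEAD-box RNA helicases of budding yeast that help ribosomes reach the start codon. The cells were SK1 strains in which the DED1 regulatory regions drove either DED1 itself or the DBP1 coding sequence in its place, called DED1 cells and DBP1 cells here. They grew vegetatively in YEPD, a rich medium, at 30C or 37C. Messenger RNA was sequenced to measure transcript abundance, and ribosome footprints were sequenced to measure the relative number of ribosomes on each coding sequence. Each library was scaled to its own depth, so a change in total mRNA or in total translation would not be seen. The stated purpose was to learn how specific each helicase is and how its effects depend on temperature. There were 20 libraries. For each strain and assay, 3 came from cultures at 30C and 2 from cultures at 37C. Depth was 3.94 to 9.69 M reads for mRNA and 4.82 to 9.39 M reads for footprints. Values are RPKM as mean ± SD over these 3 or 2 cultures, and translation efficiency is footprint RPKM divided by mRNA RPKM. Fold changes and adjusted p-values come from limma fits of log2(RPKM + 1), so a fold can differ from the ratio of the printed means. Rose and fell are used only for genes past that test.

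The swapped genes themselves showed which helicase each culture made. DED1 (YOR204W) in DED1 cells at 30C had an mRNA level of 51.1 ± 2.88 RPKM (SD, n = 3) and 671 ± 65.6 RPKM of footprints. In DBP1 cells its mRNA lay between 0.0765 and 3.19 RPKM over the 5 cultures and its footprints between 1.29 and 2.6 RPKM. DBP1 (YPL119C) in DBP1 cells at 30C had 119 ± 11 RPKM of mRNA (SD, n = 3) and 496 ± 20.0 RPKM of footprints. Its native locus gave 3.64 to 6.50 RPKM of mRNA and 2.99 to 8.07 RPKM of footprints in the 5 cultures of DED1 cells.

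The first question was whether the same regulatory regions yielded equal transcript and equal translation of both coding sequences. DBP1 cells held 2.32 times as much DBP1 mRNA as DED1 cells held DED1 mRNA at 30C. The ribosome load per transcript went the other way. Translation efficiency was 13.2 ± 2.0 for DED1 in DED1 cells and 4.20 ± 0.219 for DBP1 in DBP1 cells (SD, n = 3), a ratio of 3.15. All 3 cultures of one strain lay apart from all 3 of the other, and a two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 cultures allow. At 37C the efficiencies were 8.64 ± 0.390 and 2.96 ± 0.335 (SD, n = 2), a ratio of 2.92. The exact permutation p was 0.333 there, the smallest that 2 against 2 allow. The mRNA and efficiency ratios are not separate results, because both hold the same mRNA values. Footprints on DED1 were only 1.35 times those on DBP1 at 30C. These ratios compare 2 coding sequences, so a difference in how fully their reads were counted would not cancel, and it was not tested.

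Footprints on the expressed helicase were fewer at 37C in both strains. DED1 footprints in DED1 cells fell 1.83-fold, to 365 ± 0.0855 RPKM, with an adjusted p of 0.00102. DBP1 footprints in DBP1 cells fell 1.55-fold, to 319 ± 6.69 RPKM, with an adjusted p of 0.000942. The native DBP1 gene of DED1 cells rose in footprints by 2.05-fold at 37C, from 3.25 ± 0.421 to 7.70 ± 0.516 RPKM. Its mRNA rose 1.35-fold with an adjusted p of 0.0250. That mRNA call ended without culture 1 at 30C, culture 2 at 30C or culture 1 at 37C, with adjusted p of 0.0520, 0.0720 and 0.203.

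**Figure D1:**
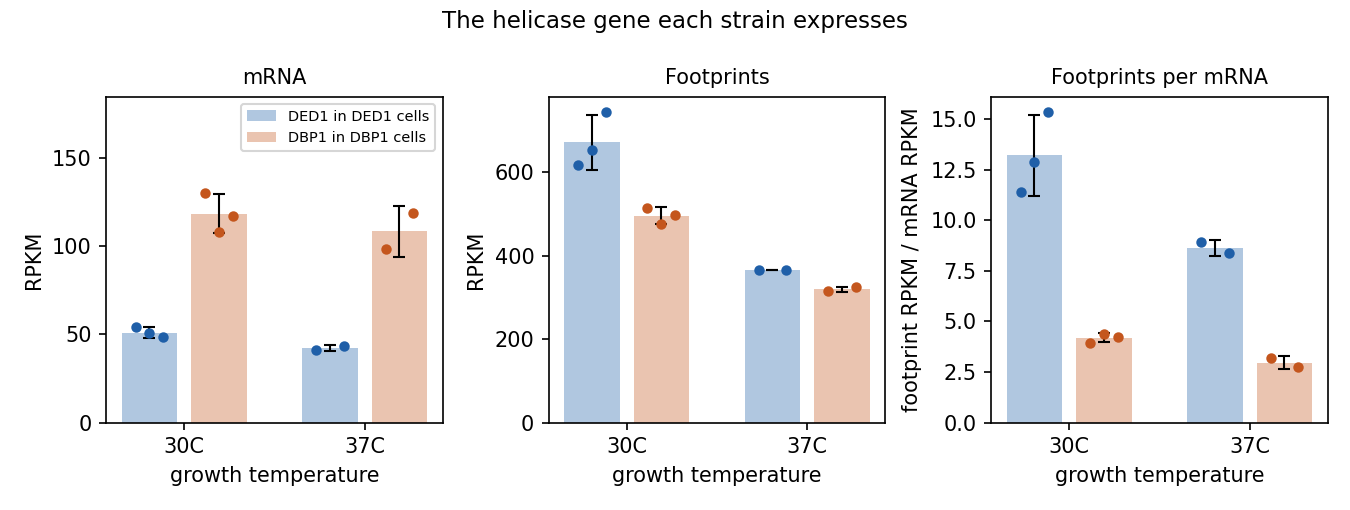
mRNA, footprints (both in RPKM) and translation efficiency of DED1 in DED1 cells and of DBP1 in DBP1 cells at 30C and 37C; bars are means, error bars SD and points single cultures. At 30C mean mRNA was 51.1 RPKM for DED1 and 119 RPKM for DBP1, and mean translation efficiency was 13.2 and 4.20.

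The comparison of DBP1 cells with DED1 cells at 30C asked what changes when Dbp1 does the work of Ded1 at the usual temperature. DBP1 cells held more mRNA of 29 of 37 general stress genes and of 30 of 33 respiratory genes. They held less mRNA of MET17, MET2 and MET16, which serve sulfur and methionine metabolism, and of 5 of 10 histone genes. No gene list passed as a whole once the correlation between its genes was estimated in place of the planned preset. No list in any comparison passed that way, so this does not show that the lists were unchanged. The footprint calls in these groups went the same way. In the fit without pairing by culture, no gene apart from the swapped helicases passed for translation efficiency, and 10 others passed with it. In mRNA, 507 of 5454 genes passed, of which 438 rose in DBP1 cells and 69 fell. With a block for the replicate number 784 passed. The count was 271 without DBP1 culture 2, 293 without DED1 culture 2 and 279 without DED1 culture 3. In footprints, 672 of 4986 genes passed, 518 of them higher and 154 lower. With median-of-ratios scaling the footprint split was 369 higher and 248 lower. The footprint count was 405, 340 and 422 without DBP1 cultures 1, 2 and 3, and 373 and 356 without DED1 cultures 2 and 3. The mRNA and footprint differences had a Pearson r of 0.889 across 4977 genes, which came from the same cultures and are not independent replicates.

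Many genes of the general stress response, controlled by Msn2 and Msn4, rose. Of 37 tested, 29 rose, 0 fell and 8 did not pass. Adjusted over the list alone, 34 rose. Their median log2 difference was 1.33, and the list test gave adjusted p = 0.185 with an estimated correlation. HSP12 (YFL014W), a small heat shock protein that binds membranes, went from 65.3 ± 42.4 to 1051 ± 198 RPKM (SD, n = 3). Its log2 difference was 4.15 ± 0.33 (SE), with an adjusted p of 0.000114, and its footprints rose 18.4-fold. CTT1 (YGR088W), the cytosolic catalase, rose 3.76-fold in mRNA and 7.93-fold in footprints. The transketolase TKL2 rose from 1.67 ± 0.220 to 21.7 ± 6.80 RPKM (SD, n = 3), glycogen phosphorylase GPH1 4.95-fold and MSC1 3.09-fold in mRNA. RTN2 rose 3.58-fold and the stress gene DDR2 7.95-fold. The call of DDR2 ended without DBP1 culture 3 or DED1 culture 2, at adjusted p of 0.0524 and 0.0549. Outside the list, FMP45 rose 7.51-fold, the secreted glycoprotein YGP1 6.21-fold and EGO4 6.13-fold. In footprints 32 of 34 general stress genes rose, 33 when adjusted over the list alone, and the list test gave adjusted p = 0.193 with an estimated correlation.

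Most genes of mitochondrial respiration rose too. All 15 tested genes of the tricarboxylic acid (TCA) cycle rose in mRNA, the same number when adjusted over the list alone, and the list test gave adjusted p = 0.158 with an estimated correlation. With median-of-ratios scaling 13 rose. CIT1 (YNR001C), the mitochondrial citrate synthase, went from 579 ± 14.9 to 1075 ± 35.7 RPKM (SD, n = 3), a log2 difference of 0.89 ± 0.07 (SE). SDH2 (YLL041C), a subunit of succinate dehydrogenase, rose 1.90-fold and the second mitochondrial citrate synthase, CIT3, 3.19-fold. Of 33 genes of the respiratory chain and ATP synthase, 30 rose, 33 when adjusted over the list alone, with adjusted p = 0.158 with an estimated correlation. Scaling by median of ratios left 18 of them past the test. The complex III subunits QCR10 and QCR6 rose 1.44-fold and 1.38-fold. In footprints 14 of 15 TCA genes and 29 of 33 respiratory genes rose, 15 and 32 when adjusted over the list alone. Their list tests gave adjusted p = 0.125 and 0.225 with an estimated correlation. HAP4, which encodes the activator of respiratory genes, rose 1.33-fold in mRNA and 1.41-fold in footprints.

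Fewer genes were lower in DBP1 cells at 30C. MET17 (YLR303W), which makes homocysteine from sulfide, fell from 169.8 ± 48.0 to 67.3 ± 10.7 RPKM (SD, n = 3), 2.45-fold, with an adjusted p of 0.00406. The methionine pathway genes MET2 and MET16 fell 1.81-fold and 1.72-fold, the phospholipase gene PLB2 1.70-fold and the cell wall gene HPF1 1.81-fold. The water channel gene AQY2 fell 2.61-fold with an adjusted p of 0.0447. Its call ended without any of DBP1 cultures 1, 2 and 3 or DED1 cultures 1 and 2, at adjusted p of 0.0698, 0.0553, 0.121, 0.102 and 0.153. Of 10 histone genes 5 fell, 7 when adjusted over the list alone, with adjusted p = 0.185 with an estimated correlation. HTA1, which encodes histone H2A, fell 1.55-fold, a call that ended at an adjusted p of 0.0529 without DBP1 culture 2. Among cytosolic ribosomal proteins, 3 of 139 genes fell in mRNA, 1 when adjusted over the list alone, with adjusted p = 0.330 with an estimated correlation. RPS9A was 1.32-fold lower. In footprints 40 of 137 of them fell, 86 when adjusted over the list alone, with adjusted p = 0.241 with an estimated correlation. No initiation factor gene passed in mRNA out of 29 tested with limma, 0 also when adjusted over the list alone, with adjusted p = 0.215 with an estimated correlation. In footprints 4 of the same 29 fell, 5 when adjusted over the list alone, with adjusted p = 0.331 with an estimated correlation.

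**Figure D2:**
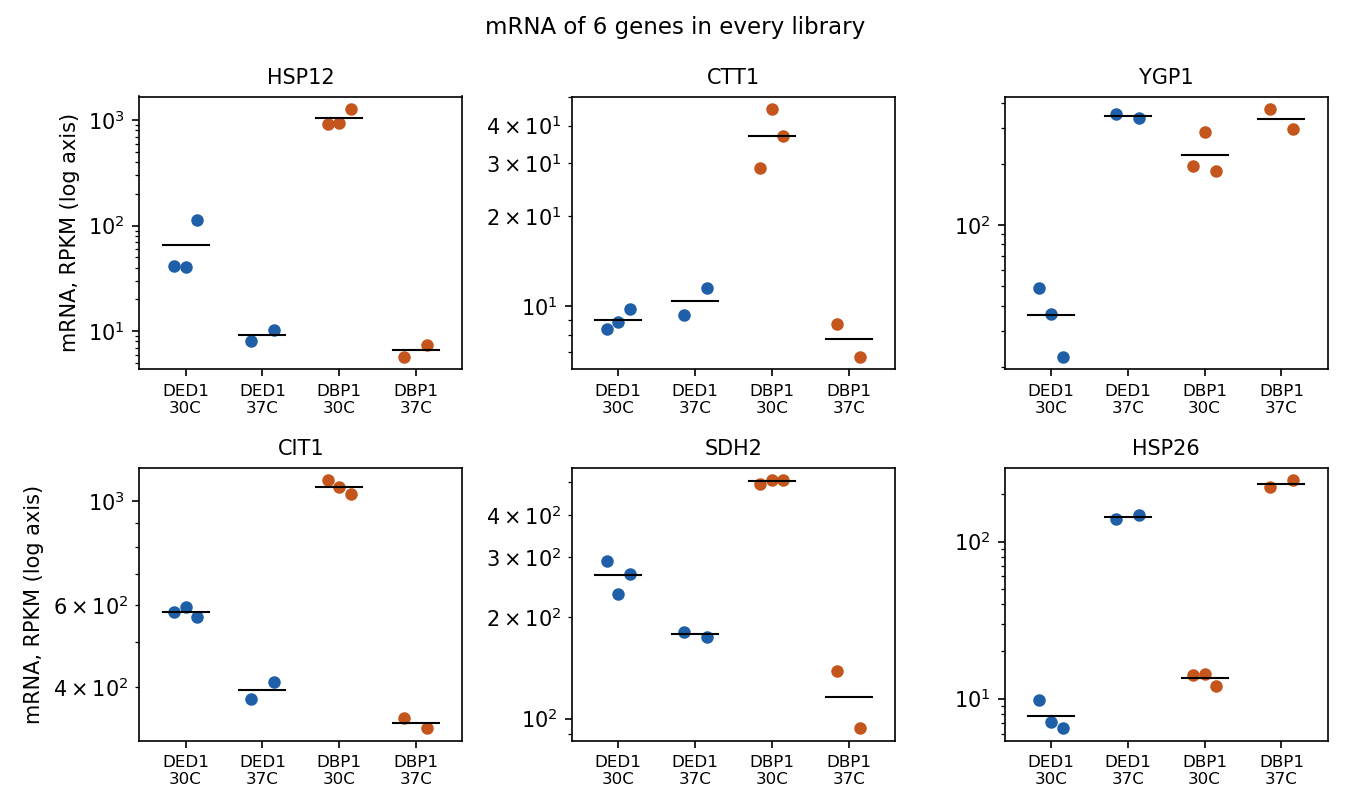
mRNA abundance (RPKM, log axis) of HSP12, CTT1, YGP1, CIT1, SDH2 and HSP26 in each of the 10 cultures, grouped by strain and temperature; points are cultures and lines group means. At 30C mean HSP12 mRNA was 65.3 RPKM in DED1 cells and 1051 RPKM in DBP1 cells.

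Translation efficiency asked whether Dbp1 loads ribosomes onto particular mRNAs more or less than Ded1 does. Of 4977 genes, 2 passed limma's test at 30C, and 153 had an unadjusted p under 0.05. The 2 genes were the swapped pair. DBP1 was 4.93-fold higher in DBP1 cells. In DED1 cells its reads came from the native locus, at 4.04 RPKM of mRNA and 3.25 RPKM of footprints. The DBP1 call thus compares the gene under different regulatory regions, and does not show how either helicase loads ribosomes. For DED1 the values in DBP1 cells were background, so no fold is given, and with a pseudocount of 0.1 its adjusted p was 0.495. When footprints and mRNA were paired by culture, 12 genes passed, 9 higher and 3 lower, and 10 of them were not the swapped genes. MSC1 and RTN2 were among these 10, higher by 0.94 and 1.47 log2. In that paired fit 4 of 34 general stress genes rose. The list test gave adjusted p = 1.52e-12 with the preset correlation and 0.0985 with an estimated correlation. GCN4 encodes the activator of amino acid genes, and its mRNA carries upstream reading frames that limit its translation. Its mRNA was 1228 ± 90.6 RPKM in DED1 cells and 1634 ± 139 RPKM in DBP1 cells (SD, n = 3), with an adjusted p of 0.0512, short of the threshold. Its footprints were 384 ± 81.2 and 611 ± 128 RPKM, with an adjusted p of 0.248. Of 11 genes with known upstream reading frames, 2 rose in mRNA, HAP4 and CPA1, the latter 1.57-fold. Adjusted over the list alone 4 rose, with adjusted p = 0.274 with an estimated correlation. On simulated data for this comparison, 50.75% of efficiency changes of 1.5-fold and 95.52% of 2-fold changes were recovered. Those were genes with a mean of at least 20 RPKM and a spread set to the median of the assay. Recovery of fainter or more variable genes was not measured. In the unpaired fit RTN2 was 2.77-fold higher in efficiency and did not pass, at an adjusted p of 0.709 (limma). A gene that did not pass is thus not shown to be unchanged.

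The same comparison at 37C asked whether the swap matters more or less when cells are warm. Few genes differed. No general stress gene passed. In footprints 7 of 33 respiratory and 3 of 47 amino acid genes were lower in DBP1 cells, of which median-of-ratios scaling left 0 and 1. In mRNA 3 of 5454 genes passed limma's test, namely DBP1, DED1 and MET28, and 576 had an unadjusted p under 0.05. MET28, which encodes a regulator of sulfur genes, fell 1.98-fold with an adjusted p of 0.0480. Its call ended without DBP1 culture 1, DED1 culture 1 or DED1 culture 2, at adjusted p of 0.0746, 0.209 and 0.183. The mRNA count was 20 without DBP1 culture 1, 9 without DBP1 culture 2 and 9 with a block for the replicate number. In footprints 48 of 4986 genes passed, 2 higher and 46 lower, and 822 had an unadjusted p under 0.05. The footprint count was 12 without DBP1 culture 2, 6 without DED1 culture 1 and 2 without DED1 culture 2, and with a block for the replicate number it was 130. No general stress gene passed in mRNA, 0 also when adjusted over the list alone, and the list test gave adjusted p = 0.793 with an estimated correlation. Their median log2 difference was -0.26.

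Among footprints at 37C, 7 of 33 respiratory genes fell, 28 when adjusted over the list alone, with adjusted p = 0.414 with an estimated correlation. Cytochrome c, CYC1, fell 1.67-fold, the complex III gene QCR8 1.44-fold and the cytochrome oxidase gene COX13 1.41-fold. Of 15 TCA genes 3 fell, 11 when adjusted over the list alone, with adjusted p = 0.414 with an estimated correlation. The succinate dehydrogenase genes SDH4 and SDH3 fell 1.61-fold and 1.50-fold. Of 47 amino acid genes under Gcn4 control 3 fell, 25 when adjusted over the list alone, with adjusted p = 0.487 with an estimated correlation. LEU1 fell 1.84-fold, MET13 2.44-fold, the oxaloacetate carrier gene OAC1 2.02-fold and MET17 2.79-fold. The elongation factor gene YEF3 rose 1.28-fold with an adjusted p of 0.0494. With median-of-ratios scaling 11 genes passed, among them 0 respiratory, 1 TCA and 1 amino acid genes. Of the 12 named footprint calls 10 ended without some culture, all but those of DED1 and DBP1. Without DBP1 culture 1, the YEF3 call ended at an adjusted p of 0.110. Without DBP1 culture 2, 9 ended at 0.0547 to 0.148. Without DED1 culture 1, 9 ended at 0.0571 to 0.172, and without DED1 culture 2, 10 ended at 0.0831 to 0.175. The mRNA of MET17 was 70.6 ± 12.2 and 29.4 ± 5.87 RPKM (SD, n = 2), and that of CYC1 981 ± 85.7 and 651 ± 17.7 RPKM, at adjusted p of 0.115 and 0.102. In translation efficiency 109 genes had an unadjusted p under 0.05. In DED1 cells the reads of DBP1 came from its native locus, at 5.80 RPKM of mRNA and 7.70 RPKM of footprints. Only DBP1 passed limma's test, 2.28-fold higher at an adjusted p of 0.0401. That call ended without DBP1 culture 1 or 2 or DED1 culture 1 or 2, at adjusted p of 0.351, 0.227, 0.484 and 0.0723. With footprints and mRNA paired by culture 0 genes passed.

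A direct test asked whether the swap acted differently at the 2 temperatures, as the difference at 37C minus the difference at 30C. In mRNA 285 of 5454 genes passed, 9 with a higher and 276 with a lower difference at 37C. With median-of-ratios scaling 163 passed, 13 higher and 150 lower, and with a block for the replicate number 595 passed, 118 higher and 477 lower. Of 37 general stress genes 19 were lower, 34 when adjusted over the list alone, with adjusted p = 0.236 with an estimated correlation. Their median interaction was -1.58 log2. For HSP12 the interaction was -4.58 ± 0.53 log2 (SE), for CTT1 -2.30 ± 0.27, for CIT1 -1.12 ± 0.11 and for SDH2 -1.56 ± 0.21. Of 33 respiratory genes 27 and of 15 TCA genes 12 were lower, 33 and 15 when adjusted over the list alone. The list tests of both gave adjusted p = 0.137 with an estimated correlation. With median-of-ratios scaling, the lower genes numbered 15 general stress, 11 respiratory and 8 TCA genes. The mRNA count was 162 and 172 without DBP1 cultures 2 and 3 at 30C, and 180 without DBP1 culture 1 at 37C. It was 177 without DED1 culture 2 at 30C, and 88 and 141 without DED1 cultures 1 and 2 at 37C.

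In footprints 596 of 4986 genes passed this test, 95 with a higher and 501 with a lower difference at 37C. With median-of-ratios scaling the split was 187 higher and 298 lower. General stress genes accounted for 27 lower of 34 tested, 32 when adjusted over the list alone, with adjusted p = 0.20 with an estimated correlation. Of 137 cytosolic ribosomal protein genes 44 were higher, 85 when adjusted over the list alone, with adjusted p = 0.198 with an estimated correlation. The footprint count was 370, 384 and 365 without DBP1 cultures 1, 2 and 3 at 30C, and 319 without DBP1 culture 2 at 37C. It was 304 and 373 without DED1 cultures 2 and 3 at 30C, and 205 and 317 without DED1 cultures 1 and 2 at 37C. No gene passed for translation efficiency with limma, with or without pairing by culture, and 113 had an unadjusted p under 0.05.

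**Figure D3:**
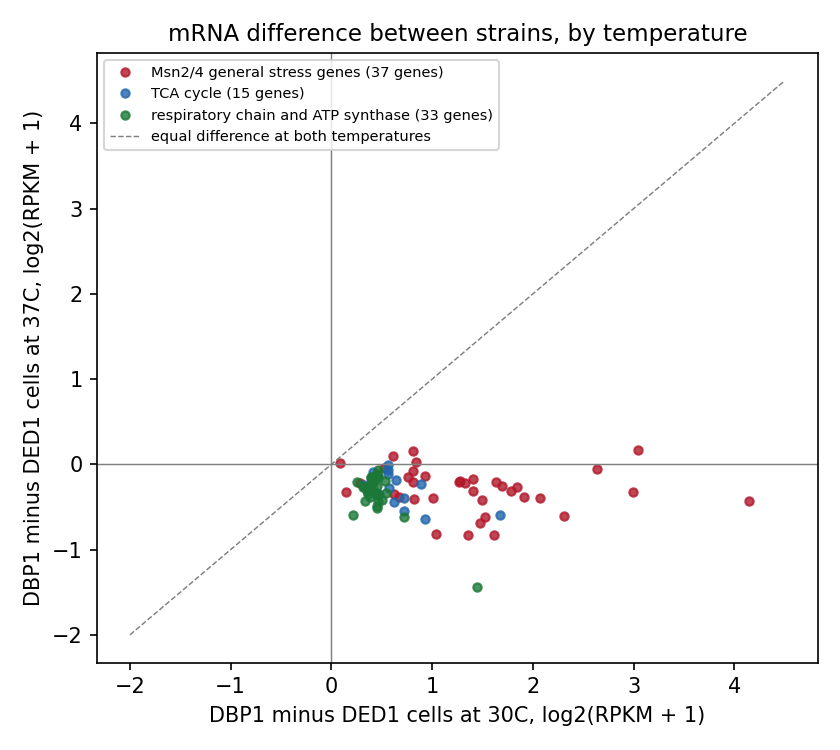
mRNA log2 difference between DBP1 and DED1 cells at 30C (x axis) and at 37C (y axis) for the tested general stress (37), TCA cycle (15) and respiratory (33) genes; each point is a gene and the dashed line marks equal differences. The general stress genes had a median of 1.33 at 30C and -0.26 at 37C.

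The comparison of 37C with 30C in DED1 cells asked how cells with the native helicase respond to growth at a raised temperature. In mRNA 20 of 31 chaperone, 25 of 37 general stress and 17 of 28 cell wall genes rose, while 2349 of all 5454 genes did. Median-of-ratios scaling left 16, 18 and 10 of them, and each list had adjusted p = 0.716 with an estimated correlation. Most genes for cytosolic and mitochondrial ribosomes, respiration and histones fell, again with no list past the test with an estimated correlation. In mRNA 2909 of 5454 genes passed, 2349 higher and 560 lower. The median gene was higher at 37C by 0.26 log2 in mRNA and 0.21 in footprints, and median-of-ratios scaling removed this shift. The mRNA split then became 926 higher and 1180 lower. In footprints 2621 of 4986 genes passed, 1942 higher and 679 lower, or 1002 and 1195 with that scaling. The footprint count was 1673 without culture 1 at 37C.

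Many chaperone genes controlled by Hsf1 rose in DED1 cells. Of 31 tested, 20 rose and 1 fell, the same numbers when adjusted over the list alone, with adjusted p = 0.716 with an estimated correlation. With median-of-ratios scaling 16 rose. HSP26 (YBR072W), a small heat shock protein, went from 7.79 ± 1.75 (SD, n = 3) to 144 ± 5.98 RPKM (SD, n = 2), a log2 change of 4.06 ± 0.15 (SE). Its footprints rose 33.1-fold. The Hsp70 gene SSA4 (YER103W) rose 5.03-fold in mRNA and 20.4-fold in footprints. Polyubiquitin, UBI4, rose 4.49-fold and the cyclophilin gene CPR6 3.18-fold. Of 37 general stress genes 25 rose and 1 fell, the same when adjusted over the list alone, with adjusted p = 0.716 with an estimated correlation. TMA10 rose 16.3-fold and the glutaredoxin gene GRX1 2.25-fold, while HSP12 was the gene that fell, 5.79-fold. With that scaling 18 rose. Of 28 cell wall integrity genes 17 rose and 3 fell, 18 and 3 when adjusted over the list alone, with adjusted p = 0.716 with an estimated correlation. PST1 rose 3.67-fold and the glucan synthase gene GSC2 2.69-fold. In footprints 25 of 36 proteasome genes rose, 29 when adjusted over the list alone, with adjusted p = 0.666 with an estimated correlation, and 3 with median-of-ratios scaling. Among these PUP2 rose 1.45-fold, and RPN4, the activator of proteasome genes, rose 2.54-fold in mRNA. Other large rises were YRO2 at 14.5-fold, MOH1 at 11.3-fold and YGP1 at 9.81-fold. For the acid phosphatase gene PHO5 the log2 change of 2.53 was 1.84 without culture 1 and 3.22 without culture 2 at 37C. The zinc transporter gene ZRT1 rose from 12.7 ± 3.93 (SD, n = 3) to 337 ± 421 RPKM (SD, n = 2). Its log2 change of 3.58 was 1.58 without culture 1 and 5.57 without culture 2 at 37C. Its mRNA and footprint calls ended without culture 1 at 37C at adjusted p of 0.0862 and 0.0611.

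Many genes for making ribosomes and for respiration fell in DED1 cells at 37C. Of 139 cytosolic ribosomal protein genes 120 fell and 1 rose, 123 and 1 when adjusted over the list alone, with adjusted p = 0.273 with an estimated correlation. RPS22B fell 3.83-fold, RPL8A 1.97-fold and RPL30 1.58-fold. Of 69 mitochondrial ribosomal protein genes 48 fell, 51 when adjusted over the list alone, with adjusted p = 0.340 with an estimated correlation. MRPL17 fell 1.80-fold in mRNA and 1.47-fold in footprints, a footprint call that ended at an adjusted p of 0.0822 without culture 1 at 37C. Of 33 respiratory genes 31 fell, the same number when adjusted over the list alone, with adjusted p = 0.126 with an estimated correlation. The ATP synthase gene ATP3 fell 2.42-fold and the cytochrome oxidase gene COX8 2.33-fold. Of 15 TCA genes 9 fell and 2 rose, the same when adjusted over the list alone, with adjusted p = 0.295 with an estimated correlation, and CIT1 fell 1.47-fold. Of 10 histone genes 8 fell, the same number when adjusted over the list alone, with adjusted p = 0.273 with an estimated correlation. Of 89 ribosome biogenesis genes 22 fell, 6 when adjusted over the list alone, with adjusted p = 0.543 with an estimated correlation. The nucleolar genes NSR1 and NOP1 fell 2.05-fold and 1.69-fold. Of 29 initiation factor genes 13 fell, 11 when adjusted over the list alone, with adjusted p = 0.295 with an estimated correlation. The eIF3 subunit TIF35 fell 1.45-fold, and the poly(A)-binding protein gene PAB1 fell 1.70-fold in footprints. With median-of-ratios scaling 131 cytosolic and 63 mitochondrial ribosomal protein genes, 59 ribosome biogenesis and 23 initiation factor genes fell. The largest falls named were the phosphate transporter gene PHO84 at 15.9-fold, the drug transporter gene QDR2 at 11.5-fold, the peptide transporter gene PTR2 at 8.47-fold and the hexose transporter gene HXT2 at 3.99-fold.

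In DBP1 cells the question was the same, with Dbp1 in place of Ded1. In mRNA 17 of 31 chaperone genes rose, while 1635 of all 5454 genes did, and median-of-ratios scaling left 12. Most respiratory, TCA, mitochondrial ribosome and amino acid genes fell, and so did 18 of 37 general stress genes. No list passed as a whole with an estimated correlation between its genes. In mRNA 2350 of 5454 genes passed, 1635 higher and 715 lower. With median-of-ratios scaling, which moved the median gene from 0.18 to 0.02 log2, 714 were higher and 1049 lower. The mRNA count was 1358 without culture 2 at 37C. In footprints 1938 of 4986 genes passed, 1059 higher and 879 lower, or 761 and 1038 with that scaling. The footprint count was 1290 without culture 2 at 37C.

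All 33 tested respiratory genes fell in mRNA in DBP1 cells, the same number when adjusted over the list alone. The list test gave adjusted p = 0.0655 with an estimated correlation, the smallest of all 380 list tests. COX4 fell 3.63-fold and ATP4 3.35-fold. Of 15 TCA genes 14 fell, 15 when adjusted over the list alone, with adjusted p = 0.102 with an estimated correlation. SDH2 fell 4.4-fold, and CIT1 went from 1075 ± 35.7 (SD, n = 3) to 335 ± 11.7 RPKM (SD, n = 2). Of 69 mitochondrial ribosomal protein genes 61 fell, 64 when adjusted over the list alone, with adjusted p = 0.427 with an estimated correlation, and MRPL10 fell 2.01-fold. Of 47 amino acid genes under Gcn4 control 35 fell and 1 rose, 36 and 2 when adjusted over the list alone, with adjusted p = 0.523 with an estimated correlation. The aspartokinase gene HOM3 fell 2.34-fold. GCN4 itself fell in footprints from 611 ± 128 (SD, n = 3) to 188 ± 145 RPKM (SD, n = 2), a log2 change of -1.92, or -2.80 without culture 1 and -1.05 without culture 2 at 37C. Its mRNA was 1634 ± 139 and 1309 ± 278 RPKM with an adjusted p of 0.0589. Of 37 general stress genes 18 fell and 3 rose, the same when adjusted over the list alone, with adjusted p = 0.727 with an estimated correlation. HSP12 fell 138-fold, from 1051 ± 198 to 6.58 ± 1.24 RPKM. CTT1 fell 4.31-fold and TKL2 4.19-fold. DDR2 fell from 48.1 ± 10.5 (SD, n = 3) to 3.73 ± 5.28 RPKM (SD, n = 2), with culture 1 at 37C at 0. Its log2 change of -4.06 was -2.52 without that culture and -5.60 without culture 2 at 37C. Outside that list FMP45 fell from 59.7 ± 19.7 (SD, n = 3) to 1.61 ± 0.346 RPKM (SD, n = 2). QDR2 fell 13.8-fold, PHO84 13.4-fold, the transcription factor gene CIN5 12.9-fold, the aminotransferase gene AGX1 12.8-fold and SIP18 7.97-fold.

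Of 31 Hsf1 chaperone genes 17 rose and 1 fell in DBP1 cells, 18 and 1 when adjusted over the list alone, with adjusted p = 0.825 with an estimated correlation. With median-of-ratios scaling 12 rose. HSP26 rose 16.3-fold, SSA4 6.78-fold and CPR6 4.11-fold in mRNA. Of 28 cell wall integrity genes 17 rose and 1 fell, 19 and 2 when adjusted over the list alone, with adjusted p = 0.825 with an estimated correlation, and scaling left 8 risen. The mannoprotein genes TIP1 and HPF1 rose 6.59-fold and 3.75-fold. ZRT1 rose from 11.5 ± 0.633 (SD, n = 3) to 659 ± 621 RPKM (SD, n = 2). Its log2 change of 5.30 was 4.14 without culture 1 and 6.46 without culture 2 at 37C. Other rises were the iron transporter gene FET4 at 7.33-fold, the hexose transporter gene HXT4 at 6.93-fold and PHO5 at 4.39-fold. Of 139 cytosolic ribosomal protein genes 32 fell and 4 rose, 12 and 3 when adjusted over the list alone, with adjusted p = 0.727 with an estimated correlation. RPS22B fell 2.23-fold and RPL8A 1.46-fold, while RPS14B rose 2.02-fold, and scaling gave 74 lower. Of 89 ribosome biogenesis genes 20 rose, 6 when adjusted over the list alone, with adjusted p = 0.879 with an estimated correlation, and 2 with median-of-ratios scaling. In footprints 24 of 36 proteasome genes rose, 25 when adjusted over the list alone, with adjusted p = 0.527 with an estimated correlation, and 12 with that scaling.

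The strains shared much of their difference between temperatures, and these comparisons have no library in common. Labels and library codes fall into separate sets by temperature, and whether both sets were grown and sequenced together is not given. Another difference between those sets could move both strains alike, so the overlap does not tell it apart from temperature. In mRNA 1278 genes rose in both strains where independent lists would share 704, and 328 fell in both where 73.4 would be shared. In footprints 852 rose and 429 fell in both, against 412 and 120 for independent lists. The shift of the median gene adds to the shared rises. With median-of-ratios scaling 409 rose and 658 fell in both in mRNA, against 121 and 227 for independent lists. In footprints that scaling gave 454 and 659, against 153 and 249. Every mRNA and footprint change named here between strains or temperatures went the same way in each pair of cultures compared, which the rule for naming the largest changes required. Paralogs such as ribosomal protein genes, HTA1, HXT4 and SSA4 can share reads, and how such reads were counted is not given in the sources used here. Ribosomal protein counts include RPP1, an RNase P subunit that its name places in that list.

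**Figure D4:**
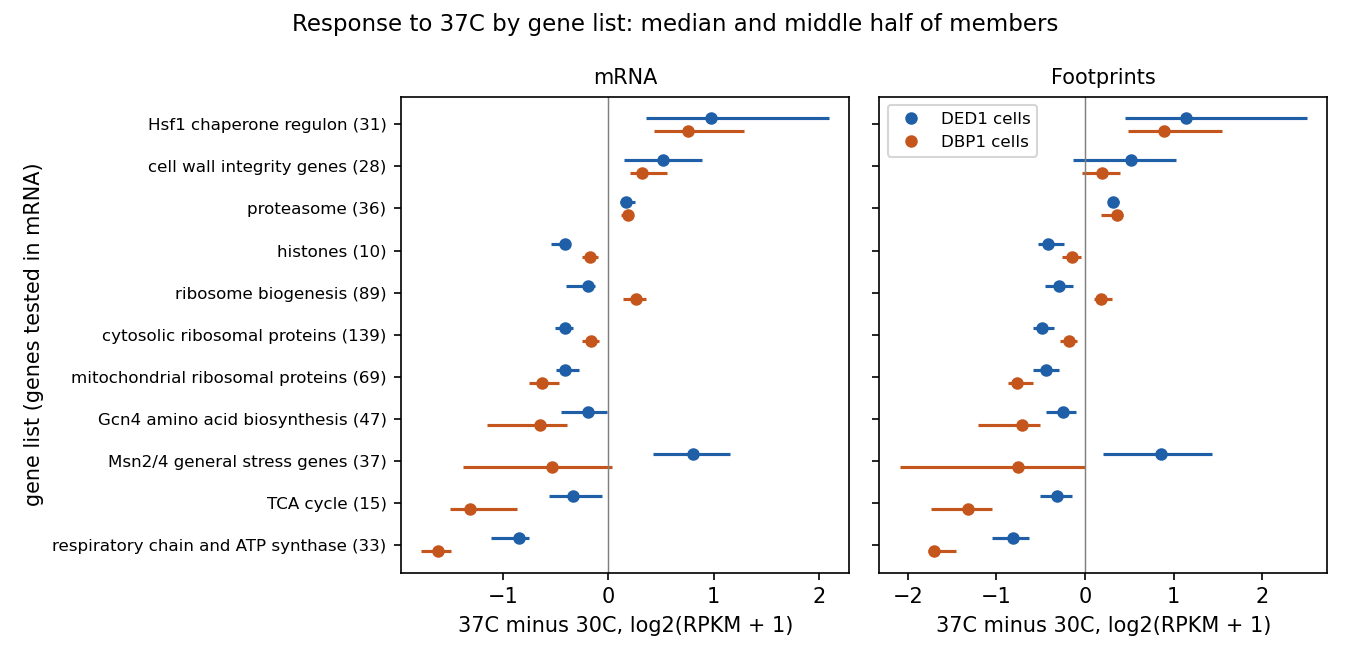
log2 change from 30C to 37C of each gene list in DED1 and DBP1 cells, in mRNA and in footprints; points are list medians over tested genes and bars span the 25th to 75th percentile. Respiratory genes had a median mRNA change of -0.85 in DED1 cells and -1.61 in DBP1 cells.

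Translation efficiency at 37C asked which mRNAs gained or lost ribosomes, relative to other mRNAs, beyond the change in their abundance. More genes fell than rose in both strains. In DED1 cells 49 of 4977 genes passed, 7 higher and 42 lower, and 594 had an unadjusted p under 0.05. With median-of-ratios scaling 11 were higher and 26 lower. With footprints and mRNA paired by culture 322 passed, 94 higher and 228 lower. SSA4 rose 4.06-fold and the glycosyltransferase gene GNT1 1.70-fold. The bromodomain gene BDF2 fell 1.84-fold, at an mRNA level of 192 ± 9.69 and 169.7 ± 7.29 RPKM, and the exonuclease gene XRN1 (YGL173C) fell 1.75-fold. Paired by culture, SSA4, XRN1, BDF2 and GNT1 passed at adjusted p of 0.000115, 0.00612, 0.00960 and 0.00995 (limma). In the unpaired fit all 4 calls ended without some culture. Without culture 2 or 3 at 30C, SSA4 and XRN1 ended at 0.0716 and 0.0626. Without culture 1 at 37C, SSA4 and XRN1 ended at 0.0922 and GNT1 at 0.0863, and without culture 2 at 37C, SSA4 ended at 0.173, XRN1 at 0.190 and BDF2 at 0.0685 (adjusted p, limma). The count was 21, 5 and 5 without cultures 1, 2 and 3 at 30C, and 4 and 5 without cultures 1 and 2 at 37C. The efficiency change fell with coding length across 4924 genes, at a Spearman rho of -0.369 in DED1 cells and -0.237 in DBP1 cells, and genes are not independent replicates. A length bias of the mRNA libraries could produce this trend, and the falls of single genes were not adjusted for length.

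In DBP1 cells 51 genes passed for translation efficiency, 3 higher and 48 lower, and 598 had an unadjusted p under 0.05. With median-of-ratios scaling 8 were higher and 29 lower. Pairing by culture gave 326 genes, 36 higher and 290 lower. GCN4 was not among the 51 genes, at an adjusted p of 0.128, but passed when paired by culture, at a log2 change of -1.59 and an adjusted p of 0.0150. Unpaired, it was -2.24 with an adjusted p of 0.0111 without culture 1 at 37C, and -0.93 with 0.388 without culture 2. Of 11 genes with known upstream reading frames 3 fell in the paired fit, and 2 did in DED1 cells, with adjusted p = 0.616 and 0.749 with an estimated correlation. SSA4 rose 4.23-fold. HAP4 fell 2.01-fold, PUF3, which encodes a protein that binds mRNAs for mitochondrial proteins, 1.82-fold, XRN1 1.63-fold and SIP18 3.62-fold. For SIP18 the log2 change of -1.86 was -2.47 without culture 1 and -1.24 without culture 2 at 37C. Paired by culture, HAP4, PUF3, XRN1 and SIP18 passed at adjusted p of 0.000692, 0.00348, 0.00706 and 0.00598 (limma). In the unpaired fit these and SSA4, 5 calls in all, also ended without some culture. Without culture 1 at 30C, SSA4, PUF3, XRN1 and SIP18 ended at 0.0585, 0.0767, 0.121 and 0.0802. Without culture 2 at 30C, SIP18 ended at 0.0773, and without culture 3 at 30C, SSA4, PUF3, XRN1 and SIP18 ended at 0.0658, 0.0731, 0.117 and 0.0749. Without culture 1 at 37C, PUF3 and XRN1 ended at 0.107 and 0.215. Without culture 2 at 37C, all 5 ended, SSA4 and HAP4 at 0.0792, PUF3 at 0.148, XRN1 at 0.215 and SIP18 at 0.368 (adjusted p, limma). The count was 2 and 1 without cultures 1 and 3 at 30C, and 20 and 0 without cultures 1 and 2 at 37C. The mRNA of HAP4 fell 1.2-fold, a call that ended without culture 1 or 2 at 30C or culture 1 or 2 at 37C, at adjusted p of 0.0963, 0.0632, 0.101 and 0.111.

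Few genes of any list passed for efficiency at 37C. Of 31 Hsf1 chaperone genes 2 rose in DED1 cells and 2 in DBP1 cells, 2 and 3 when adjusted over the list alone. The list tests gave adjusted p = 0.952 and 0.962 with an estimated correlation. Paired by culture, 5 rose in each strain, with adjusted p = 0.570 and 0.201 with an estimated correlation. Of 15 genes for P-body and stress granule proteins, which gather untranslated mRNA, 1 fell in each strain, 5 when adjusted over the list alone. The list tests gave adjusted p = 0.462 in DED1 and 0.237 in DBP1 cells with an estimated correlation. Paired by culture, 2 fell in DED1 cells and 3 in DBP1 cells, with adjusted p = 0.570 and 0.201 with an estimated correlation. Of 34 general stress genes 7 fell and 0 rose in DBP1 cells when paired by culture, the largest paired count of any list, with adjusted p = 0.766 with an estimated correlation. Of the efficiency calls, 3 genes rose and 17 fell in both strains, where independent lists would share 0.00422 and 0.405. With median-of-ratios scaling 4 rose and 11 fell in both. The efficiency change also fell with coding length in both strains, and a length bias of the mRNA libraries could produce that. Such a bias could move both strains alike, so this overlap does not tell it apart from a change in translation. None of the 154 list calls made with the preset correlation held with an estimated one. The p-values measure the spread between these cultures, whose independence the labels do not state beyond a replicate number.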

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

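The results here were picked because the effect of the helicase swap differed between the temperatures by a direct test of that difference. Of the tests of explanations below, the omission of cultures and the subsets of 2 against 2 cultures were written down before their results, and the others were chosen after the results were seen.

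The swap changed fewer genes at 37C, and 285 genes in mRNA and 596 in footprints passed the direct test for a different effect. Among the genes named in the report, the mRNA interaction was negative for HSP12 at -4.58 log2, TKL2 at -2.87, GPH1 at -2.91, CTT1 at -2.30, RTN2 at -2.10 and MSC1 at -1.84. It was also negative for FMP45 at -3.17, EGO4 at -3.17, YGP1 at -2.69, YRO2 at -2.50, MOH1 at -2.38, SIP18 at -2.29, AGX1 at -2.33 and CIN5 at -1.96.

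Genes of the TCA cycle and the respiratory chain also gave negative values. The interaction was -2.27 log2 for CIT3, -1.56 for SDH2, -1.12 for CIT1, -1.11 for SDH4 and -1.07 for SDH3. It was -0.93 for COX13, -0.80 for CYC1, -0.72 for QCR10, -0.71 for COX4 and -0.61 for QCR6. ATP3 and ATP4 both had -0.60, COX8 -0.59 and QCR8 -0.58. Outside these groups it was -1.05 for CPA1, -0.88 for MET28, -0.81 for GSC2 and -0.78 for HAP4. With median-of-ratios scaling 7 of the 35 named calls ended, those of ATP3, ATP4, COX4, COX8, GSC2, QCR6 and QCR8, at adjusted p from 0.0586 to 0.0979. Their values were nearer 0 after scaling, from -0.72 ± 0.19 log2 (SE) for GSC2 to -0.47 ± 0.14 for QCR8, against -0.81 ± 0.20 and -0.58 ± 0.12 before. It was positive for PLB2 at 1.27, HPF1 at 1.17 and NOP1 at 0.66.

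Some of these calls ended when a culture was left out. Without 1 of the 10 cultures, 11 of 35 named interaction calls ended in at least 1 case, at adjusted p from 0.0515 to 0.148. The 11 were ATP3, ATP4, COX4, COX8, GSC2, HPF1, MET28, NOP1, QCR6, QCR8 and YRO2. Without DBP1 cultures 1, 2 and 3 at 30C, 3 calls ended at 0.0705 to 0.0760, 7 at 0.0516 to 0.0748 and 8 at 0.0515 to 0.0770. Without DBP1 cultures 1 and 2 at 37C, 6 ended at 0.0624 to 0.112 and 6 at 0.0517 to 0.109. Without DED1 cultures 1, 2 and 3 at 30C, 2 ended at 0.0531 to 0.0569, 7 at 0.0583 to 0.0758 and 2 at 0.0614 to 0.0662. Without DED1 cultures 1 and 2 at 37C, 8 ended at 0.0520 to 0.148 and 9 at 0.0521 to 0.123. The mRNA count of 285 became 162 and 172 without DBP1 cultures 2 and 3 at 30C, 180 without DBP1 culture 1 at 37C, 177 without DED1 culture 2 at 30C, and 88 and 141 without DED1 cultures 1 and 2 at 37C. The footprint count of 596 became 370, 384 and 365 without DBP1 cultures 1, 2 and 3 at 30C, and 319 without DBP1 culture 2 at 37C. It became 304 and 373 without DED1 cultures 2 and 3 at 30C, and 205 and 317 without DED1 cultures 1 and 2 at 37C. Genes named for a difference at 30C share the 30C libraries with this test. The members of the general stress list were fixed without them. The attention given to that list followed its difference at 30C, which also enters the interaction, so its interaction is not independent of that difference.

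The smaller effect at 37C could come from the 2 cultures per group there. Each of the 9 subsets of 2 against 2 cultures at 30C gave at least 122 mRNA calls, with a median of 188, against 3 at 37C, which speaks against that. A larger spread at 37C would hide differences without shrinking them, but the median interaction of the general stress genes was -1.58 log2. Median-of-ratios scaling took the lower genes from 19 to 15 of 37 general stress, from 27 to 11 of 33 respiratory and from 12 to 8 of 15 TCA genes, and their median interactions from -1.58 to -1.48, -0.66 to -0.56 and -0.82 to -0.72 log2, which speaks against scaling as the whole cause. A difference that depends on the helicase and the temperature may remain, and so may unlabelled differences in how the 30C cultures of each strain grew.

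For the higher level of general stress genes in DBP1 cells at 30C, 3 candidate sources besides the helicase were examined, and others were not tested. Among those not tested, footprints on the expressed helicase differed at 30C, at 671 RPKM for DED1 and 496 RPKM for DBP1. Median-of-ratios scaling left 28 of 37 genes risen against 29, which speaks against scaling. One deviating culture is unlikely to be the source, because the lowest count without a single culture was 21 of 37, reached without DBP1 culture 2 and without DED1 culture 3. Lower glucose in the DBP1 cultures at harvest could raise stress and respiratory genes together. The glucose-repressed hexose transporter genes had a median log2 difference of -0.45, but only HXT2 and HXT4 of 4 were abundant enough to test, so this stays open.

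The 6 cultures at 30C allow 10 splits into 3 against 3, too few for a share under 0.05. The real split gave 507 mRNA, 672 footprint and 2 efficiency calls, and the highest count of any other split was 0 in each. Every other split mixes the strains, so the strain difference adds to the spread within its groups and lowers its count. The 2 efficiency calls were the swapped genes. These counts therefore cannot decide whether the difference arose by chance.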

How the results depend on the processing

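Alternatives were fixed in advance except the precision weights, which were chosen after the data had been seen. Counts are given here where an alternative moved them by over 1.5 times, with the full range of counts when each culture was left out. The cause was not tested in any case.

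Median-of-ratios scaling between libraries took the footprint calls between strains at 37C from 48 to 11 and the mRNA interaction calls from 285 to 163. Dropping the abundance filter gave 30 footprint calls between strains at 37C, 0 efficiency calls between strains at 37C in place of 1, 1 efficiency interaction call in place of 0, and 84 efficiency calls for temperature in DBP1 cells in place of 51. A filter at a mean of 20 RPKM gave 10 efficiency calls for temperature in DED1 cells in place of 49 and 21 in DBP1 cells. Fitting only the groups compared gave 2 footprint and 0 efficiency calls between strains at 37C. The same fit gave 5 and 2 efficiency calls for temperature in DED1 and DBP1 cells. A pseudocount of 0.1 gave 1 efficiency call between strains at 30C in place of 2 and 0 at 37C, and a pseudocount of 5 gave 2 at 37C. Precision weights gave 29 footprint calls between strains at 37C, and 1 and 0 efficiency calls between strains at 30C and 37C. The 154 list calls became 0 with an estimated correlation.

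With a block for the replicate number, mRNA calls between strains went from 507 to 784 at 30C and from 3 to 9 at 37C. Footprint calls between strains at 37C went from 48 to 130 and mRNA interaction calls from 285 to 595. Cultures of the 2 strains with the same number share only that number. The r between their deviations ran from -0.16 to 0.48 over 10 pairs with a median of 0.40. With 2 cultures per group at 37C, both pairs of an assay repeat the same r, so the 10 are not independent. At 30C alone r ran from -0.16 to 0.47. Not every culture correlated best with its own number. With footprints and mRNA paired by culture, efficiency calls went from 2 to 12 between strains at 30C and from 1 to 0 at 37C. For temperature the pairing took them from 49 to 322 in DED1 cells and from 51 to 326 in DBP1 cells. The block moved no other count by over 1.5 times.

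Each culture was left out in turn, and a lone culture left in a group was assumed to vary like the other groups. For strains at 30C, calls ran from 271 to 579 in mRNA, 340 to 713 in footprints and 2 to 3 in efficiency. For strains at 37C they ran from 2 to 20, 2 to 61 and 0 to 0. For temperature in DED1 cells they ran from 1977 to 2787 in mRNA, 1673 to 2489 in footprints and 4 to 21 in efficiency. In DBP1 cells they ran from 1358 to 2005, 1290 to 1683 and 0 to 34. For the interaction they ran from 88 to 333 in mRNA, 205 to 702 in footprints and 0 to 0 in efficiency.

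Depth was lowest at 3.94 M reads in mRNA and 4.82 M in footprints, and genes under the abundance filter stayed untested. A planned count-based tool was not run because the table holds RPKM. For the genes named in the text, 106 of 125 mRNA calls, 94 of 106 footprint calls and 1 of 12 efficiency calls were kept in every alternative. Of 5 mRNA, 1 footprint and 1 efficiency results named without a call, 4, 0 and 1 gained one in some alternative. None reversed.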

Other observations

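The patterns in this part were found while reading the values, and their tests were chosen after the result was seen unless stated otherwise.

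The change in translation efficiency from 30C to 37C fell with coding length. Between the strains at 30C the Spearman rho was -0.152 over 4924 genes. That comparison shares the 30C libraries of each strain with the temperature comparisons. The trend in DBP1 cells, at a rho of -0.237, uses no DED1 library, so the DED1 libraries at 30C do not account for it. A length trend was also present without a change of temperature, so whether the trend belongs to temperature stays open. The median log2 change with temperature was 0.09 in DED1 cells and -0.01 in DBP1 cells for the 20% of genes with the shortest coding sequence, up to 675 nt, and -0.16 and -0.17 for the 20% with the longest, from 2106 nt.

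A length bias of the mRNA libraries at 37C could produce this. The mRNA change rose with length, at a Spearman rho of 0.182 in DED1 and 0.318 in DBP1 cells, while the footprint change had a rho of -0.0420 and 0.137, and both values fit such a bias. Low abundance of long genes could contribute, and given both levels the rank correlation of efficiency with length was -0.274 in DED1 and -0.0982 in DBP1 cells, which leaves it open. A single deviating culture may affect the strength of the trend, since the rank correlation over the 12 pairs of a 30C and a 37C culture ran from -0.458 to -0.0959. It was negative in all 12 pairs, so no single culture accounts for its direction. The abundance and culture tests were written down before their results, the other after, and no biological explanation was tested.

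Among zinc-responsive genes, 5 of 9 tested rose in mRNA at 37C in DED1 cells, where 2349 of all 5454 genes did, and 6 in DBP1 cells, where 1635 did. There were 4 in each with median-of-ratios scaling, when 1 fell in DED1 cells. ZRT1 differed widely between the cultures at 37C, at 337 ± 421 RPKM in DED1 and 659 ± 621 in DBP1 cells (SD, n = 2). Of 11 tested genes of thiamine synthesis and uptake, 10 rose in DED1 cells and 9 in DBP1 cells, or 10 and 7 with that scaling, when 1 fell in DBP1 cells. No test of these lists as a whole was made. PHO3 went from 149 ± 25.2 RPKM at 30C (SD, n = 3) to 463 ± 101 RPKM at 37C (SD, n = 2) in DED1 cells.

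Of sulfur amino acid genes, 9 of 26 tested fell in mRNA and 10 of 22 in footprints in DBP1 cells at 30C, with medians of -0.27 and -0.34 log2. At 37C 1 fell in mRNA and 2 in footprints, but the medians were -0.35 and -0.51 log2. The median interaction was -0.01 log2 in mRNA and -0.05 in footprints. For single genes, 2 had a lower difference at 37C in mRNA, and 1 a higher and 1 a lower one in footprints. LEU2 and HIS3 were listed at 0 RPKM in all 20 libraries.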
